A study of Arabis alpina with 12 samples.

How the data were processed

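Chromatin profiles of 4 kinds and 1 mRNA profile were made from young leaves of Arabis alpina, accession Pajares, a perennial relative of Arabidopsis. The plants grew in soil under 16 h of light and 8 h of dark at 22.5 °C, per the labels. Chromatin immunoprecipitation (ChIP-seq) with antibodies to H3K4me3, H3K27me3 and H3K27me1 has 2 libraries per mark and shares 1 input library. Immunoprecipitation of methylated DNA (MeDIP-seq, 5mC) has 2 libraries and 2 input libraries, and the mRNA profile has 1 library, for 12 libraries in all. The labels do not say whether the replicates came from separate plants.

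Each mark is represented by 1 list of domains for the whole series. Whether and how the 2 replicates of each mark were combined in it is not given in the sources used here. Bowtie and SICER, a caller of broad enriched domains, are named in the submitters' processing notes, without versions. The genome build and the calling parameters are not given in the sources used here. Domain starts and lengths are whole multiples of 150 bp in the lists of H3K4me3, H3K27me1 and 5mC and of 300 bp in the list of H3K27me3. The fourth column of each deposited domain list is a whole-number score per domain, unlabelled by the authors. SICER island lists commonly hold the number of tags per island in that place, but no header says so here. The score was therefore used only within a list, as a score and as a score per kb of domain. The lists give no p-value, fold enrichment or input value, so false positive rates could not be set against these scores.

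The deposited mRNA table gives, by its name, the read coverage of the exons of each gene as a signal that is never below 1, with the start and end of each gene. Of the genes listed, 2185 hold exactly 1. A mean over covered bases only would give such a floor, but no header states it, and the authors' scaling to depth, if any, is not stated. Which genes were left out of the table is not given in the sources used here, so "listed genes" below means the 24657 genes in it. The table gives no strand, gene name or description, and no reference genome was used here. Gene lists by function had been fixed beforehand (photosynthesis, transcription factor families, transposon domains and others), but the files do not pair identifiers with names. None of those lists could be tested, and identifiers are given as they stand in the files. Sequencing depth is unknown for every library.

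Domain starts were read as 0-based and domain ends as inclusive, since domains begin at 0 on some scaffolds and their lengths are then whole windows. Coordinates are printed 1-based on the authors' assembly. The length of each sequence was taken as the furthest end of any domain or listed gene on it, which gave 284.5 Mb over 3000 sequences. Of this, 234.6 Mb lay on 8 chromosomes and 49.9 Mb on 2992 scaffolds. Marks were held on the 150 bp grid. Overlap between marks was measured in bp and divided by the mean overlap after the domains of 1 mark had been rotated by a random distance within each sequence (circular shift, 1000 shifts). A two-sided permutation p-value was taken from the shifts and adjusted by the Benjamini-Hochberg method over the 6 pairs. The smallest p-value that 1000 shifts can give is 0.002, and 100 shifts, used for alternatives, give 0.02 before adjustment. Assembly gaps and unmappable sequence were not masked, which tends to raise the folds, and the shifts treat positions along a sequence as exchangeable. For bins touching or not touching listed genes, those bins alone were joined within each sequence before the shifts. For 1000 shifts the unadjusted p-values of all pairs were also 0.002.

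A listed gene was counted as marked when at least 200 bp of its span, start to end, lay in domains of the mark. Shares carry exact (Clopper-Pearson) 95% intervals, which cover counting error only. mRNA coverage was compared by medians with order-statistic 95% intervals, and as differences of log2(coverage + 1). With 1 mRNA library, genes are not replicates and no p-value was computed across genes. Instead the median of each set was placed among the medians of 10000 random gene sets of the same size, matched on decile of gene span. Coverage of marks along the chromosomes was correlated across 500 kb bins, with p-values from 1000 rotations of the bins within chromosomes. Upstream and downstream flanks could not be told apart without strand and were pooled.

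Before the data were examined, the genes and domains to be named were set by rule: the 5 longest domains per mark, the 10 genes of highest mRNA coverage, and the 5 highest within genes with H3K27me3 but not H3K4me3, with 5mC over at least 50% of the span, and with both H3K4me3 and H3K27me3. Without gene names, the rule allowed at most 2 identifiers per set. The alternatives set at that time were another overlap minimum, domains of at least the median length, the upper 50% of domains by score (for the extent covered), random placement, overlaps on chromosomes only, other bin widths, 5 groups of genes by mRNA, a pseudocount of 0.1 and genes of at least 500 bp. Splits by score per kb and by gene context, the split by score for overlaps, and chromosomes only for genes were added after seeing the data. The planned flank of 1 kb upstream was run as 1 kb on each side. Restricting to genes with coverage above 0 changed nothing, since no listed gene is below 1. The overlap statistic was checked on simulated data in which 0%, 25% or 50% of the 37507 H3K4me3 domains stayed in place and the others were rotated. The test gave p under 0.05 in 0, 20 and 20 of 20 runs, with median folds of 1.00, 2.99 and 5.13. The 0% runs were built by the same rotation as the test, so they cannot show false calls from unmasked gaps or unmappable sequence. No planted overlap with a fold between 1.00 and 2.99 was tried. For the gene sets, 200 of 24657 genes with shuffled mRNA values were multiplied by 1, 1.5, 2 or 4, which gave percentiles of 56.5, 100, 100 and 100 among random sets. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.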

Results

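Domains of H3K4me3, H3K27me3, H3K27me1 and 5mC were compared with each other, with gene position and with mRNA coverage in young leaves of Arabis alpina. H3K4me3 is a histone mark typical of active gene starts, H3K27me3 is the mark of Polycomb repression, and H3K27me1 and cytosine methylation (5mC) are marks of plant heterochromatin. Each mark was given as 1 domain list and not as 1 list per library, so no value below has a replicate error. Depth is unknown, and p-values measure departure from random position along the sequences.

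5mC covered the most sequence and H3K27me3 had the fewest domains. The 61122 domains of 5mC covered 57.3 Mb, 20.1% of the assembly extent. The 56694 domains of H3K27me1 covered 48.6 Mb (17.1%). H3K4me3 had 37507 domains over 26.4 Mb (9.28%), and H3K27me3 had 23093 domains over 26.4 Mb (9.27%). Median domain length was 900 bp for H3K27me3 and 600 bp for each of the other marks. Unplaced scaffolds made up 17.5% of the extent but held 29.1% of the H3K27me1 bp and 27.01% of the 5mC bp, against 15.9% for H3K4me3 and 18.0% for H3K27me3. The mRNA table listed 24657 genes with a median span of 2091 bp and a median coverage of 5.77 (quartiles 2.33 and 12.9).

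The longest domains differed in what else lay on them. The longest 5mC domain was 17.85 kb on scaff_73658_1 (41401 to 59250), touched no listed gene and lay 72.3% inside H3K27me1. The longest H3K27me3 domain was 16.8 kb on chromosome 7 (1479001 to 1495800), also without a listed gene or H3K4me3. Of the 5 longest H3K4me3 domains, 3 lay wholly inside domains of all the other marks and touched no listed gene, among them the longest of all, 8.4 kb on chromosome 3 (26375701 to 26384100). A 6.6 kb H3K4me3 domain on chromosome 3 (191701 to 198300) was free of the other marks and ran over 5 listed genes. The longest H3K27me1 domain, 13.95 kb on chromosome 2 (2339551 to 2353500), lay wholly inside 5mC, carried 10 listed genes and had 30.4 times the median score per kb of its list.

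The distribution along the chromosomes separated H3K27me1 and 5mC from listed genes and from H3K27me3. Across 470 bins of 500 kb, the shares covered by H3K27me1 and 5mC rose and fell together (Pearson r = 0.99, Spearman rho = 0.99). Both ran against listed genes, with rho = -0.90 for H3K27me1 and rho = -0.90 for 5mC (r = -0.87 and -0.88). H3K27me3 ran against 5mC (rho = -0.62, r = -0.56) and with listed genes (rho = 0.45, r = 0.38). These 5 relations had adjusted permutation p = 0.00285 for both coefficients, over 10 relations tested, and held their sign within each of the 8 chromosomes. H3K4me3 was only weakly related to 5mC (rho = -0.25, adjusted permutation p = 0.0150, r = -0.25). Within chromosomes rho for this pair ranged from -0.38 to 0.08, and in 100 kb bins it was -0.11 (adjusted permutation p = 0.0425). H3K4me3 was related to listed genes more clearly (rho = 0.46, adjusted permutation p = 0.00285, r = 0.53), and no relation to H3K27me3 was found (rho = 0.019, adjusted permutation p = 0.59, r = 0.0024). For H3K4me3 and H3K27me1 rho was -0.22 (adjusted permutation p = 0.0289, r = -0.21), ranging within chromosomes from -0.35 to 0.098, and H3K27me3 with H3K27me1 gave rho = -0.61 (adjusted permutation p = 0.00285, r = -0.55). Without the 2 bins farthest from the median, r stayed at 0.99 for H3K27me1 with 5mC, at -0.58 for H3K27me3 with 5mC and at 0.51 for H3K4me3 with listed genes. In 100 kb bins, H3K4me3 with H3K27me3 gave rho = -0.089 (adjusted permutation p = 0.00285), H3K4me3 with H3K27me1 -0.075 and H3K27me3 with listed genes 0.086 (adjusted permutation p = 0.29 for both), and H3K27me3 was less opposed to 5mC (-0.29) and to H3K27me1 (-0.27, adjusted permutation p = 0.00285 for both). Before adjustment the p-values were 0.002 for the relations at 0.00285, 0.012 for H3K4me3 with 5mC and 0.026 for H3K4me3 with H3K27me1. Neighbouring bins are not independent, and the rotations keep that dependence.

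**Figure D1:**
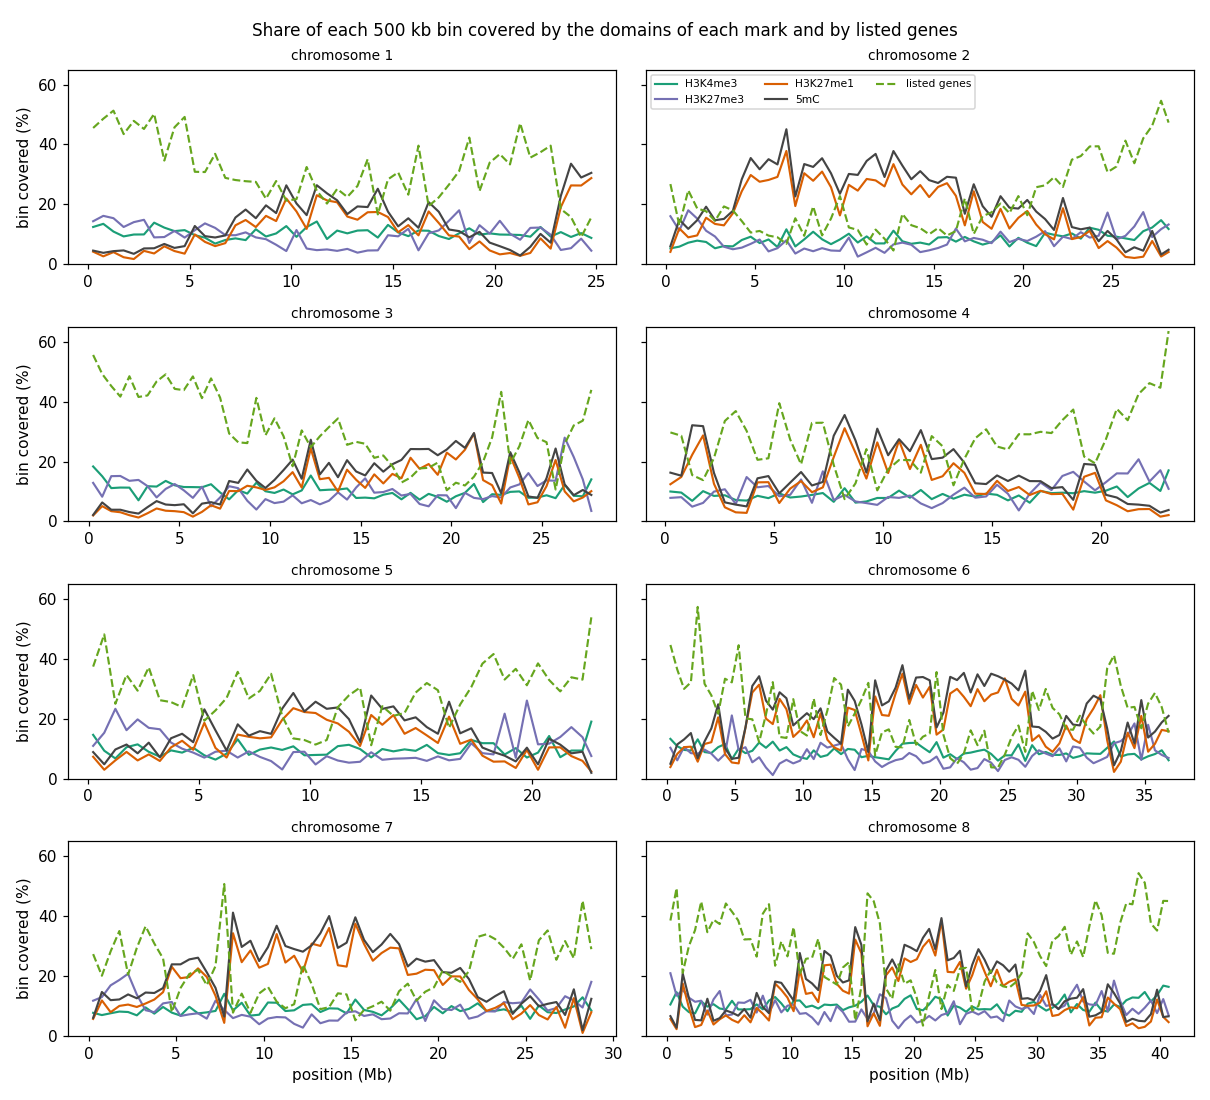
Share of each 500 kb bin covered by domains of each mark (solid lines) and by listed genes (dashed line), in percent, against position in Mb on the 8 chromosomes. H3K27me1 and 5mC track each other and are high where listed genes are sparse.

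The richest and poorest bins gave the scale of this division. In the 117 bins with most 5mC, 5mC covered 30.7% ± 3.98 (SD, n = 117 bins), H3K27me1 26.5% ± 4.16, H3K27me3 6.17% ± 1.86 and listed genes 13.4% ± 4.87. In the 118 bins with least 5mC, the values in that order were 6.47% ± 2.15 (SD, n = 118 bins), 4.63% ± 1.85, 11.96% ± 4.01 and 40.1% ± 7.67. H3K4me3 covered 9.19% ± 1.97 of the former and 10.6% ± 2.58 of the latter. The bin with the most 5mC lay on chromosome 2 (6499351 to 6999300), at 45.1% 5mC, 37.8% H3K27me1 and 6.81% listed genes; this bin and the chromosomes named next were picked after their values were seen. Chromosomes 2, 6 and 7 had the highest 5mC coverage (21.6%, 22.03% and 21.2%) and 74.8, 77.9 and 75.4 listed genes per Mb. Chromosome 1 had the lowest (13.9%) and 114.4 listed genes per Mb.

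Relative to listed genes, H3K4me3 was the only one of the 4 marks in excess over gene spans. Of its bp, 60.3% lay in the spans of listed genes, 2.54 times the level after circular shifts, and 4.01% in the 2 kb flanks, 0.21 times that level. H3K27me3 over gene spans was at 0.70, H3K27me1 at 0.21 and 5mC at 0.20 times the shifted level. In the 2 kb flanks H3K27me3 was at 0.83, H3K27me1 at 0.43 and 5mC at 0.64 times. Further from listed genes H3K27me3 was at 1.17, H3K27me1 at 1.38 and 5mC at 1.35 times, and H3K4me3 was at 0.62 times. Each of these 12 folds had an adjusted permutation p = 0.002, the smallest that 1000 shifts can give. No listed gene has coverage below 1, so genes without mRNA signal may be missing from the list. The folds hold for listed genes only, and such a selection could shift them. A mark was counted at an end when it covered at least 150 bp of the outermost 300 bp of the span. In listed genes of at least 2 kb, H3K4me3 sat at 1 end in 86.5% of 10790 marked genes (exact 95% interval 85.9% to 87.2%) and at both ends in 2.04% (1.78% to 2.32%). H3K27me3 sat at 1 end in 52.0% of 1705 marked genes (49.6% to 54.4%) and at both ends in 18.5% (16.7% to 20.5%). It covered a median of 37.1% of their span, against 24.6% for H3K4me3. No chance level was set for the shares at 1 or both ends.

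H3K4me3 marked most listed genes and the other marks few. H3K4me3 was on 18794 of 24657 genes, 76.2% (exact 95% interval 75.7% to 76.8%), against 29.5% after shifts. H3K27me3 was on 3235 genes, 13.1% (12.7% to 13.5%), against 20.99% after shifts. 5mC was on 1335 genes, 5.41% (5.14% to 5.70%), and H3K27me1 on 1134 genes, 4.599% (4.34% to 4.87%), against 36.2% and 30.2%. Every one of these 4 departures had adjusted permutation p = 0.002, the smallest possible. Genes outside the list were not counted, so shares among all genes of the species are not given. Requiring 50% of the span instead of 200 bp lowered the shares to 22.8% for H3K4me3, 7.46% for H3K27me3, 2.11% for 5mC and 1.88% for H3K27me1. With 1 kb added on each side they were 80.4%, 19.3%, 20.8% and 10.97%.

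H3K27me1 and 5mC overlapped strongly at every scale examined. They shared 33.6 Mb, which was 69.0% of the H3K27me1 bp and 58.6% of the 5mC bp and 2.78 times the shifted level (adjusted permutation p = 0.002). Over bins touching listed genes the fold was 4.35, and over bins touching no listed gene it was 2.41 (adjusted permutation p = 0.0238 and 0.0198, from 100 shifts). At the level of genes, 828 carried both marks, 13.5 times the 61.4 that independent lists of that size would share.

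H3K4me3 overlapped H3K27me1, 5mC and H3K27me3 beyond the shifted level away from listed genes, and not over them. Over the whole extent it shared 9.41 Mb with H3K27me1, 6.45 Mb with 5mC and 4.25 Mb with H3K27me3, which were 1.98, 1.17 and 1.69 times the shifted levels (adjusted permutation p = 0.002 each). Over bins touching listed genes the folds were 1.02 with H3K27me1 (adjusted permutation p = 0.50), 0.67 with 5mC and 0.77 with H3K27me3 (adjusted permutation p = 0.0238 for both). Over bins touching no listed gene they were 3.24, 1.96 and 3.11 (adjusted permutation p = 0.0198 each). Of the 10.5 Mb of H3K4me3 that touched no listed gene, 84.9% lay inside H3K27me1, 57.9% inside 5mC and 33.0% inside H3K27me3. Of the 15.9 Mb over listed genes, 3.19%, 2.36% and 4.99% did. Over the whole extent, H3K4me3 with 5mC lay mostly where H3K27me1 was called too. This was 3.94 Mb with H3K27me1 and 2.13 Mb with all the marks. Without H3K27me1 it was 0.303 Mb, and 0.0747 Mb with H3K27me3 added, although 5mC alone covered 22.3 Mb. H3K27me3 shared 7.21 Mb with H3K27me1 (1.63 times the shifted level) and 6.24 Mb with 5mC (1.15 to 1.25 times over 95% of the shifts, adjusted permutation p = 0.002 for both). H3K27me3 with 5mC also lay mostly inside H3K27me1, with 2.94 Mb, and 2.13 Mb under all the marks. Outside H3K27me1 it was 1.09 Mb, and 0.0747 Mb with H3K4me3 added. No fold was computed for 5mC outside H3K27me1. Across 500 kb bins H3K27me3 ran against both H3K27me1 and 5mC (rho = -0.61 and -0.62).

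H3K4me3 domains that lay inside H3K27me1, 5mC and H3K27me3 were mostly those of low score per kb. The 17186 H3K4me3 domains that touched no listed gene had a median score of 441.7 per kb (order-statistic 95% interval 440 to 443), and the 20321 that touched one had 889.3 per kb (882 to 898). In the lowest of 10 groups of H3K4me3 domains by score per kb, 79.1% of bp lay inside H3K27me1, 62.0% inside 5mC and 10.5% over listed genes. In the highest group the values were 1.70%, 1.81% and 96.5%. The 3 long H3K4me3 domains named above as wholly inside all the other marks were exceptions. They had 2.28, 3.36 and 1.37 times the median score per kb of the list. When only the upper 50% of each list by score per kb was kept, the folds of H3K4me3 turned to 0.91 with H3K27me1, 0.56 with 5mC and 0.89 with H3K27me3 (adjusted permutation p = 0.0238 each). In the upper 50% by score, not divided by length, H3K4me3 stayed above the shifted level at 1.60 with H3K27me1 and 1.31 with H3K27me3, and was at 0.86 with 5mC (adjusted permutation p = 0.0198 each). By score per kb the fold of H3K27me3 with 5mC fell to 1.02 (adjusted permutation p = 0.63), and that of H3K27me1 with 5mC was 3.20. These splits by score and by gene context were chosen after seeing the data.

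**Figure D2:**
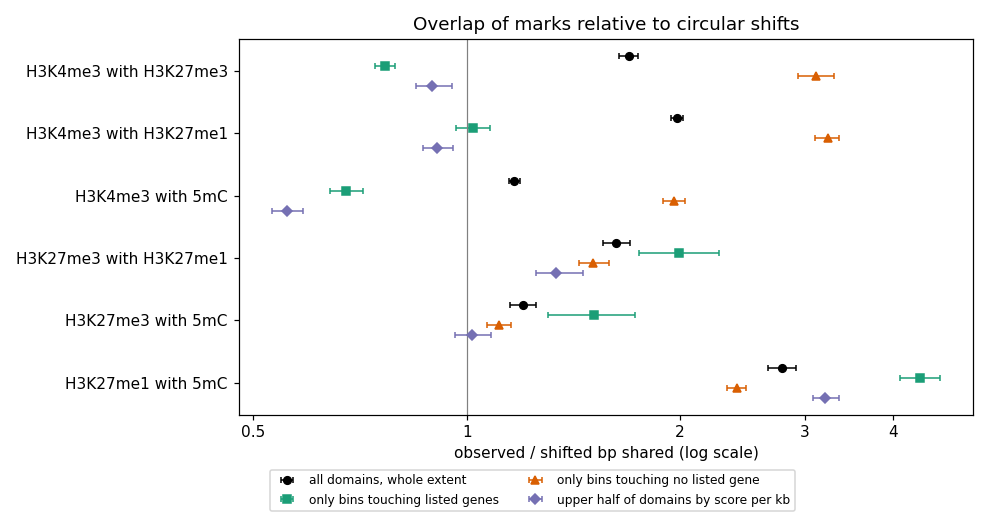
Observed bp shared by each pair of marks divided by the level after circular shifts, on a log axis; bars span 95% of the shifts, and colours mark all domains, bins touching listed genes, bins touching no listed gene, and the upper 50% of domains by score per kb. H3K4me3 pairs lie above 1 away from genes and at or below about 1 over genes and among domains of high score per kb.

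**Figure D3:**
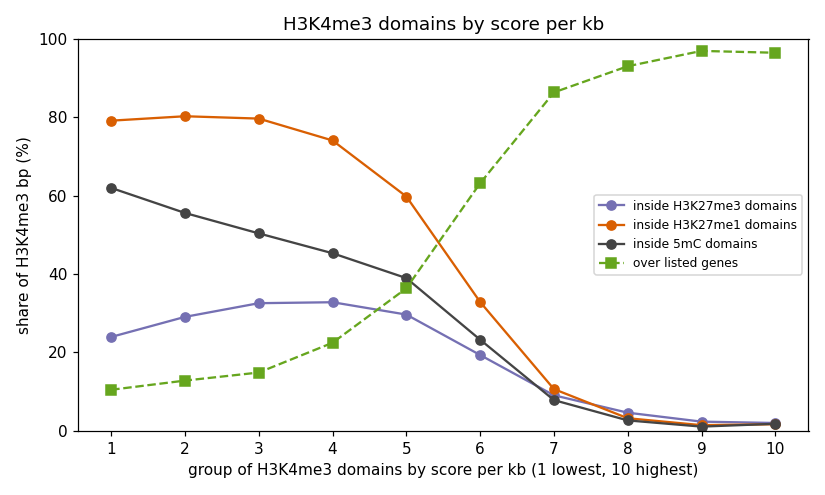
Share of H3K4me3 bp, in percent, that lies inside domains of the other marks (circles) or over listed genes (squares), for 10 groups of H3K4me3 domains by score per kb. Groups of low score per kb lie mostly inside H3K27me1, and groups of high score per kb over listed genes.

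The marks over a gene went with its mRNA coverage in this library. Median coverage was 7.49 (95% interval 7.37 to 7.62) for genes with H3K4me3 and 1.76 (1.71 to 1.80) for those without, a difference of 1.62 in log2(coverage + 1). With and without H3K27me3 the medians were 1.90 (1.82 to 1.98) and 6.46 (6.34 to 6.57), a log2 difference of -1.36. With and without H3K27me1 they were 1.37 (1.26 to 1.46) and 6.07 (5.96 to 6.18), a difference of -1.58. For 5mC they were 1.88 (1.71 to 2.04) and 6.04 (5.94 to 6.15), a difference of -1.29. The median with H3K4me3 lay above those of all 10000 random sets matched on gene span (highest 5.97). The medians with H3K27me3, H3K27me1 and 5mC lay below all of theirs (lowest 5.18, 4.78 and 4.85). Coverage of 1, the lowest value listed, was held by 3.03% of genes with H3K4me3, 25.3% with H3K27me3, 33.1% with 5mC and 39.8% with H3K27me1.

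From the lowest to the highest of 10 groups of genes by mRNA coverage, the share with H3K4me3 went from 27.5% (exact 95% interval 25.7% to 29.3%) to 93.7% (92.7% to 94.6%). The share with H3K27me3 went from 36.9% (35.0% to 38.9%) to 6.82% (5.85% to 7.88%). H3K27me1 went from 19.5% to 1.22% and 5mC from 18.9% to 1.70%. Most of the change lay in the lower groups: in the fifth group, with coverage of 4.20 to 5.77, H3K4me3 was already on 86.4% of genes and H3K27me3 on 7.75%.

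**Figure D4:**
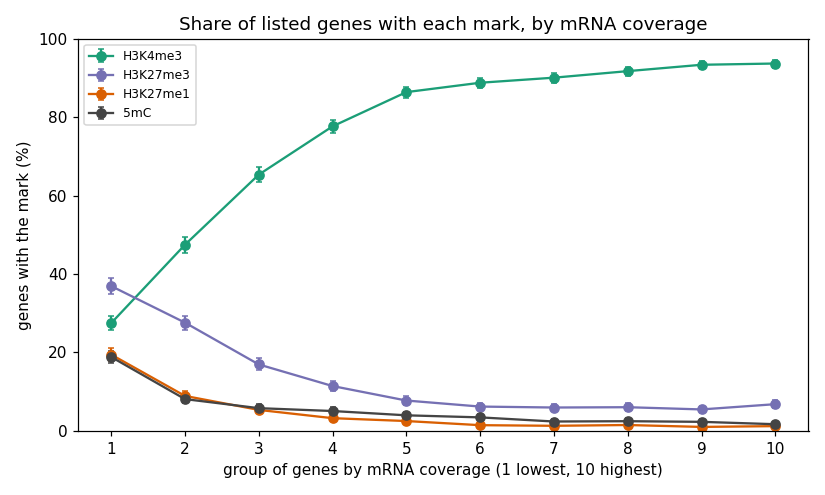
Share of listed genes with each mark, in percent, in 10 equal groups of genes by mRNA coverage; bars are exact 95% intervals. H3K4me3 rises from 27.5% to 93.7%, and the other marks are most frequent in the lowest group.

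Genes with both H3K4me3 and H3K27me3 had coverage between those with either mark alone. Among genes without H3K27me1 and 5mC, the median was 8.05 (95% interval 7.87 to 8.20) for the 16545 with H3K4me3 alone, 3.98 (3.65 to 4.38) for the 1232 with both, and 1.48 (1.41 to 1.55) for the 1568 with H3K27me3 alone. The 3671 genes with no mark had a median of 2.03 (1.96 to 2.13). At 50% of the span as the overlap minimum, 17084 genes had no mark and their median, 5.47, was above the 4.85 of genes with both marks. In all, 1521 genes carried both marks, 0.62 times the 2466 that independent lists of that size would share. The 292 genes with H3K4me3 and 5mC only had a median of 5.90 (5.29 to 6.61), at percentile 52.3 of random sets. The 310 with H3K4me3, H3K27me1 and 5mC had a median of 1.75 (1.42 to 2.00). The 245 genes with H3K27me1 and 5mC only, and the 201 with all the marks, had a median of 1.

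**Figure D5:**
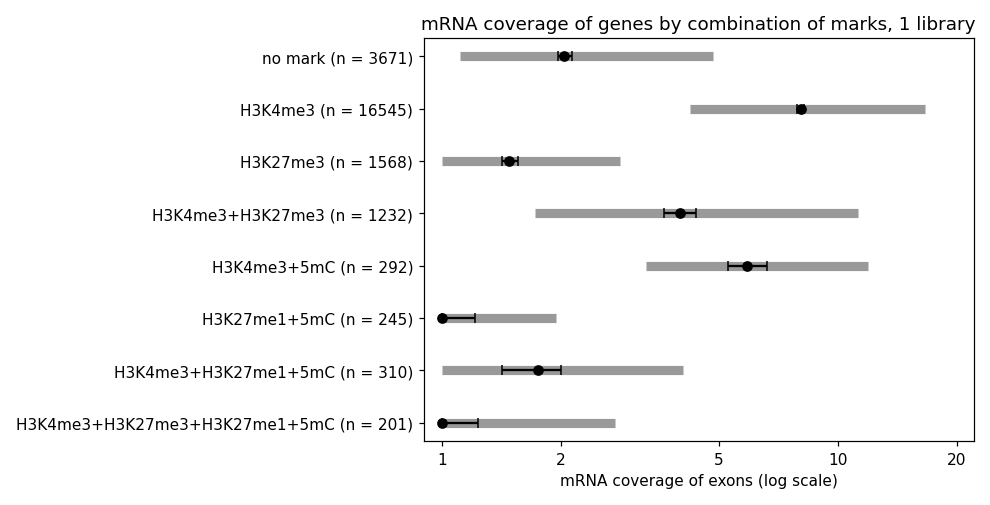
mRNA coverage of exons (log axis) for listed genes by the marks on them; points are medians with 95% order-statistic intervals and grey bars are quartiles, n being genes of 1 library. Medians run from 8.05 for H3K4me3 alone through 3.98 with H3K27me3 added to 1.48 for H3K27me3 alone.

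Of the 10 genes with the highest mRNA coverage, 8 carried H3K4me3, 1 of these also H3K27me3, and none H3K27me1 or 5mC. The other 2 had spans under 200 bp and touched no domain of any mark. The highest were Aa_G248920 (chromosome 1, 21220050 to 21221054, coverage 12378) and its neighbour Aa_G248930 (21216948 to 21218015, coverage 11265), with H3K4me3 over 99.9% and 93.9% of their spans. Those 10 genes held 11.6% of the summed coverage. Among genes with H3K27me3 and without H3K4me3, Aa_G113000 on chromosome 8 (17488007 to 17491027) had the highest coverage, 471.8, with H3K27me3 over 100% of its span. Aa_G438690 on scaff_55026_1 (6206 to 7273) followed with 314.3 and H3K27me3 over 93.2%. Among genes with both H3K4me3 and H3K27me3, Aa_G719360 on chromosome 8 (35330380 to 35331765) reached 3649, and Aa_G15430 on the same chromosome (16670250 to 16671094) reached 2011.

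5mC covered at least 50% of the span in 521 listed genes. Their median coverage was 1 (95% interval 1 to 1.104), 85.4% of them also carried H3K27me1, and 53.6% carried H3K4me3. The 5 with the highest coverage all lay in the 1 domain on chromosome 2 named above, and all were wholly covered by 5mC and H3K27me1 and free of H3K4me3 and H3K27me3. They were led by Aa_G288930 (2342633 to 2343737, coverage 464.6) and Aa_G288970 (2349232 to 2350256, coverage 436.0). Each of the 10 listed genes on that domain was above the median of all listed genes, with coverage from 9.10 to 464.6, and its 5mC score per kb was 19.5 times the median of the 5mC list.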

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

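Of 178 alternative values, 113 kept their direction and, where tested, their side of the threshold, or without a test stayed within their interval. Of the others, 54 moved outside it, 4 lost their call and 7 reversed. The size of tested values was not held to a limit: by score per kb, H3K4me3 over 2 kb from listed genes went from 0.62 to 0.16 times the shifted level. No paired analysis was possible because each mark has 1 domain list and not 1 per replicate. For the same reason leaving out a replicate and a replicate block were not run. Tests of gene groups were not run for want of names, genes above 0 are all the listed genes, and 1 kb upstream was run as 1 kb on each side. Depth is unknown. Tests chosen after seeing the data were the overlaps by score and gene context, everything by score per kb, and genes on the 8 chromosomes alone. The cause of a change was not tested except where named.

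For the overlap of marks, random placement, chromosomes only, longer domains and counting overlapped domains kept every direction and call. H3K4me3 with 5mC turned to 0.86 among domains in the upper 50% by score and 0.56 by score per kb. By score, H3K4me3 stayed at 1.60 with H3K27me1 and 1.31 with H3K27me3. By score per kb H3K4me3 also turned to 0.89 with H3K27me3 and 0.91 with H3K27me1, and H3K27me3 with 5mC lost its call at 1.02. Over bins touching listed genes, H3K4me3 turned to 0.77 with H3K27me3 and 0.67 with 5mC, and lost its call with H3K27me1 at 1.02. In 100 kb bins, rho for H3K4me3 with H3K27me3 turned to -0.089, while H3K4me3 with H3K27me1 (-0.075) and H3K27me3 with listed genes (0.086) lost their calls. In 1 Mb bins none changed. All 24 alternatives for marks around genes kept direction and call.

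Other values moved under fewer domains, other spans or another overlap minimum. The extent covered by domains of at least the median length was 7.58% for H3K4me3, 7.63% for H3K27me3, 14.3% for H3K27me1 and 17.3% for 5mC. In the upper 50% by score it was 6.33%, 6.87%, 12.9% and 16.1%. In the same order of marks, the listed genes marked were 22.8%, 7.46%, 1.88% and 2.11% at 50% of the span, and 80.4%, 19.3%, 10.97% and 20.8% with 1 kb on each side. With domains of at least the median length they were 65.03%, 9.48%, 3.35% and 4.04%, and by score per kb 65.5%, 9.18%, 2.97% and 3.83%. At 1 bp of overlap they were 77.4% for H3K4me3, 4.90% for H3K27me1 and 6.98% for 5mC, with H3K27me3 inside its interval.

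Every log2 difference of mRNA medians kept its sign. For H3K4me3 it was 1.01 at 50% of the span, 1.56 with longer domains, 1.65 for genes of at least 500 bp, 2.03 with a pseudocount of 0.1 and 1.69 on the chromosomes. For H3K27me3 it was -1.31 by score per kb and -1.71 with the pseudocount of 0.1. For H3K27me1 it was -1.79 at 50% of the span, -1.69 with longer domains, -1.71 by score per kb and -2.07 with that pseudocount. For 5mC it was -1.06 at 1 bp, -1.79 at 50%, -1.46 with longer domains and -1.63 with that pseudocount. At 50% of the span the median coverage was 5.47 for genes with no mark, 11.5 with H3K4me3 alone, 1.59 with H3K27me3 alone and 4.85 with both. By score per kb these were 2.35, 8.55, 1.59 and 5.01. In 5 groups by mRNA, the highest minus the lowest was 56.1 percentage points for H3K4me3, -26.1 for H3K27me3, -13.1 for H3K27me1 and -11.5 for 5mC.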

Other observations

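Tests of shared background, of H3K4me3 and H3K27me3 on 1 gene, of skipped identifiers and of neighbouring genes were set before their results were seen; those of genes like the listed ones, of merged copies and of the chromosome 2 region were chosen afterwards.

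Genes with H3K27me3 lay next to each other more often than shuffled marks did. Of neighbouring listed genes, 675 pairs both carried H3K27me3, 1.60 times (1.47 to 1.74) the 422.6 of marks shuffled within each sequence (highest of 1000 shuffles 484, permutation p = 0.002, the smallest possible). A single domain reached both genes in 46 of these pairs, and the other 629 were still 1.49 times the shuffled mean. For 5mC, 160 pairs both carried the mark, 1.83 times the shuffled 87.4 (highest 110, permutation p = 0.002), and 119 without a shared domain were 1.36 times. The shuffles do not keep the gradients of H3K27me3 and 5mC along the chromosomes, so clustering at that scale is included for both marks.

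H3K27me3 lay mostly away from listed genes: 68.4% of its bp was over 2 kb from any. That region is 58.2% of the extent, so the excess was small, 1.17 times the shifted level, and the shares of H3K27me1 (89.0%) and 5mC (85.5%) were higher. A candidate explanation is that part of it lies on gene models that the table does not list. Identifiers rise in steps along the sequences, so skipped numbers between neighbours may mark such models. In 2857 intervals with 1 to 5 skipped numbers, H3K27me3 coverage was 12.7%, against 6.40% in 10787 intervals with none. Matched on interval length the ratio was 1.83 (bootstrap 95% interval 1.66 to 2.03), as this explanation needs. The ratio was 2.08 for H3K4me3, 1.38 for H3K27me1 and 1.26 for 5mC, so the intervals are not special to H3K27me3, and what the skipped numbers stand for was not tested.

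H3K4me3 domains away from listed genes lay inside H3K27me1 and 5mC, although H3K4me3 is a mark of active genes. Of this H3K4me3, 84.9% lay inside H3K27me1, against 3.19% over listed genes, but that share is the pattern itself and does not decide whether unlisted genes are a source. They stay open: H3K4me3 coverage in intervals with skipped numbers was 2.08 times that in intervals with none (1.88 to 2.35). Merged sequence copies, which would raise every mark, stay open too. 5mC domains at least 50% covered by H3K4me3 had 1.09 times the score per kb of the others (bootstrap 95% interval 1.07 to 1.104). This is short of the 1.5 set as needed and under the bound of 1.2 first set against this explanation, which was lowered to 1 after the ratio had been seen. Other values rose or fell with score per kb. From the lowest to the highest of 10 groups by score per kb, the share inside H3K4me3 rose from 7.33% to 18.5% of 5mC bp and from 4.36% to 28.6% of H3K27me1 bp. In such groups the share inside H3K27me3 rose from 6.78% to 17.4% of 5mC bp and from 5.44% to 22.2% of H3K27me1 bp. The share inside H3K27me1 fell from 58.7% to 11.5% of H3K27me3 bp. Strong H3K27me3 domains outside H3K27me1 would give this fall with or without merged copies, so it does not decide. Background shared by the ChIP lists, which have 1 input library, remains a candidate explanation. Inside H3K27me1 away from genes, H3K4me3 and H3K27me3 still coincided at 2.15 times the shifted level (2.08 to 2.22 over 95% of the shifts). 5mC has inputs of its own. Over the whole extent, H3K4me3 and 5mC alone shared 0.303 Mb, against 3.94 Mb where H3K27me1 was called too. A chromatin state that truly carries the ChIP marks together, or a mixture of cells or repeat copies, could give the same values. No biological explanation was tested, as the design has no group that separates them.

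Genes with both H3K4me3 and H3K27me3 had a median coverage of 3.34, and 78.0% of them (exact 95% interval 75.9% to 80.1%) had at least 200 bp under both marks. The called domains thus overlapped on most of these genes, but no chance level was set for this share. Over all bins touching listed genes, H3K4me3 and H3K27me3 shared 0.77 times the shifted level. The share therefore does not decide whether the marks lie on different parts of a gene. The H3K4me3 score per kb over genes with both marks was 1.35 times that of domains away from genes (1.32 to 1.397), above the weak kind. It was, however, 0.63 times that of genes with H3K4me3 and no H3K27me3. A mixture of leaf cells in different states and both marks on the same nucleosomes may each give this, and neither was tested.

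The chromosome 2 region from 2339401 to 2353500 had the highest score per kb in the lists of both 5mC (19.5 times the median) and H3K27me1 (30.4 times), and its 10 genes were well covered in mRNA. Many copies of the sequence placed at 1 position of the assembly would raise scores in separate libraries alike. The H3K27me1 value does not decide this, since the region was picked out by it. The absence of the region from the H3K4me3 and H3K27me3 lists does not decide it either. Those lists hold called domains only, without read counts or input values. Copies that raised a ChIP library and its input alike could leave no domain to call. The H3K27me1 libraries share that input and a domain was called there, so this account alone does not cover H3K27me1. A very strong local enrichment of both marks stays open too, since neither the sequence nor input values were used here, and no biological explanation was tested.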
